A study of Mus musculus with 9 samples.

How the data were processed

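Total RNA from mouse ovaries was measured on Illumina expression BeadChips in 3 groups: wild type (WT), a premature ovarian failure model (POF), and ovaries of recipients of transplanted spermatogonial stem cells (SSCTR). Per the labels, all samples are of strain C57BL/6, RNA was extracted with Trizol and cleaned on a column with DNase treatment, and biotinylated cRNA was hybridized. The labels number 3 replicates per group and do not say whether these are separate animals, how ovarian failure was induced, or when the ovaries were taken. The sample titles name the SSCTR samples as recipients, without saying whether these had ovarian failure before the transplant. GenomeStudio is the only tool that the submitters' processing notes name; its version is not given in the sources used here, and neither are a genome build, the chip or the slide.

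The authors deposited 2 tables. Per the file headers, the first holds for each of 9 columns an average signal and a detection p-value. From their range, the signals are intensities on a linear scale. The headers do not define the detection p-value, taken here as the share of negative control beads at or above the probe. The name of the first table calls it non-normalized, yet the sorted intensities of replicates 2 and 3 of all groups lie within 0.541% of each other. The deposited values of these 6 arrays were therefore already brought to 1 distribution, without background subtraction. The second deposited table holds normalized intensities. From the values, it is a quantile normalization of all 9 intensity columns, which matches 99.99% of its values within a tolerance of 1e-04 of the value.

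In each group the signal of replicate 1 is the mean of replicates 2 and 3 times a factor that takes only 6 values in WT, 17 in SSCTR and 9 in POF. Where the detection p-values are not 0, that of replicate 1 is their mean times the same factor. The comparisons therefore use the 6 arrays of replicates 2 and 3, so n = 2 in each group. The number of arrays limits the precision of every value. A fit of all 9 columns, which was the plan before these columns were examined, is kept as an alternative.

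The 45281 probes carry 1 gene symbol (34885 probes), several (18) or none (10378). The symbols of 34807 probes were checked through their Entrez identifiers, and the named probes cover 19057 symbols. Intensities were processed with neqc of limma 3.58.1 in R 4.3.3, which estimates the background from the detection p-values, corrects it by normexp with an offset of 16, normalizes by quantiles and takes log2. A probe entered where its detection p was under 0.05 on at least 2 of the 6 arrays, the counterpart of the planned 3 of 9; 19394 probes did. Among the probes of a gene that entered, the one with the highest mean log2 value stands for the gene. This left 13872 features, of which 11053 are named genes and 2819 are probes with no symbol or several, which were tested and counted but not named.

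The 3 groups were fitted in 1 limma model with equal array weights and a constant empirical Bayes prior (prior degrees of freedom 5.64, residual 3). Genes past the threshold have a Benjamini-Hochberg adjusted p under 0.05 over all 13872 features. Values are log2 changes with the standard error (SE) of the moderated fit, or group means with the standard deviation (SD) of 2 arrays. A gene or probe not above background on 1 or both arrays of the dimmer group gets a bound, written as "at least": the mean of the brighter group against, for each array of the dimmer group, the higher of the probe's own value and the lowest value among the detected probes. Every adjusted p of a gene comes from limma. Over the 6 arrays, deviations of replicates with the same number did not go together across groups (r = -0.0171, -0.0628 and -0.00259 over 13872 features, which are not independent replicates), so the samples were treated as unpaired.

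The design, the gene lists, the rule for named genes and all alternatives but those said to be added later were fixed before the data were examined. The 28 lists cover cell types of the ovary, germ cells, other cells the tissue could hold, pathways, and signs of tissue handling. They hold genes of the oocyte, germ cells in general, spermatogonia, meiosis, spermatids, the Y chromosome, granulosa cells, luteal steroid synthesis, theca and interstitial cells, cholesterol synthesis, hedgehog signalling, Sertoli cells, collagen matrix, cell cycle, p53 targets, macrophages, lymphocytes, interferon response, erythroid cells, endothelium, smooth muscle, adipocytes, oviduct epithelium, surface epithelium, ribosomal proteins, oxidative phosphorylation, immediate early and heat shock genes. Lists with at least 5 measured genes were tested with camera of limma, two-sided, with a preset correlation of 0.01 and adjusted over the lists of a comparison; its p with an estimated correlation is printed beside. The text names, for each comparison, the 6 largest rises and falls among genes past the threshold whose groups do not overlap, up to 3 members of each list by adjusted p (or the brightest member where none passed), and Zp3, Gdf9, Ddx4, Fshr, Amh, Lhcgr, Cyp17a1, Star, Ddx3y and Eif2s3y. Lhcgr and Ddx3y, which no probe names, were not analysed here.

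The comparisons share arrays. The covariance and correlation of their log2 changes are therefore set beside 100 simulations of unchanged groups with the same sharing, and overlaps beside that of independent lists. In simulated log2 values with known changes, each gene varied by its moderated spread from the fit. Background correction, normalization and the detection filter were not simulated. The fit recovered 75.7% of genes changed by 1 on the log2 scale between POF and WT and 100% of those changed by 2, with 5 false calls. Of genes changed by 0.5 it recovered 3.23%, and 6.35% between SSCTR and WT, so that most changes of that size do not pass. In the simulated data 5 of 5 shifted lists and no unshifted list were called. The simulated genes varied independently, so this cannot show how the list test fares where the genes of a list go together. Alternatives were no background correction, the authors' normalized values, an offset of 50, median scaling, no detection filter, a detection p under 0.01 on all arrays, the arrays of the groups compared alone, replicate number as a block, array weights, a fold threshold, an intensity trend with a robust prior, the mean over a gene's probes, an estimated correlation in camera, and leaving out each array. Chip or slide as a block was not run, since neither is given in the sources used here. Splits of the samples were not counted for the fits over all genes, since the groups hold 2 arrays; the Y-linked mean has an exact permutation test. Figures were drawn with matplotlib 3.10.9.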

Results

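Gene expression was measured in ovaries of wild-type mice (WT), of a premature ovarian failure model (POF), and of recipients of transplanted spermatogonial stem cells (SSCTR), with 2 measured arrays per group. Spermatogonial stem cells are the germline stem cells of the testis. Probes above background numbered 17752 and 18019 on the WT arrays, 16546 and 16040 on the SSCTR arrays, and 17855 and 18041 on the POF arrays. Across genes, which are not independent replicates, the mean correlation of SSCTR with WT arrays was 0.978. POF arrays correlated with WT at 0.963 and with SSCTR at 0.959, and the arrays of a group correlated with each other at 0.988 to 0.989. The first principal component held 52.9% of the variance and set POF apart from both other groups; the second held 22.9% and separated WT from SSCTR.

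The comparison of POF with WT asks what the failure model changed in the ovary. POF ovaries held less RNA of oocyte and dividing-cell genes and more RNA of macrophage, oviduct and surface epithelium genes. None of these list calls holds with an estimated correlation: adjusted p = 0.0542 (oocyte), adjusted p = 0.0661 (cell cycle), adjusted p = 0.0542 (macrophage), adjusted p = 0.0605 (oviduct) and adjusted p = 0.128 (surface epithelium). Gdf9, a growth factor secreted by the oocyte, was 6.81-fold lower in POF (7.35 ± 0.10 against 10.12 ± 0.05 on the log2 scale, SD, n = 2), and Nobox, a transcription factor of the oocyte, was 7.91-fold lower. Zp3, a protein of the egg coat, was 2.55-fold lower (adjusted p = 0.00278). In the other direction, Ovgp1, the oviduct-specific glycoprotein, was at least 85.8-fold higher on its brightest probe, which was above background on 1 of 2 WT arrays (11.25 ± 0.13 against 4.69 ± 0.35, SD, n = 2), and Lcn2, a secreted lipocalin, was 10.2-fold higher.

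Among named genes, 1312 passed the threshold in POF against WT: 745 were higher in POF and 567 were lower. Of these, 627 changed at least 2-fold, 426 up and 201 down. A further 344 probes without a single gene symbol passed. The balance of named genes turned with a detection p under 0.01 on all arrays, where 616 were higher in POF and 653 lower. The largest rises with separate groups were A2ml1 (at least 85.4-fold), Ovgp1, Ltf (lactotransferrin, 26.7-fold), 2810025M15Rik (23.8-fold), Mia (22.2-fold) and Padi1 (at least 18.8-fold). The second Ovgp1 probe, below background in WT, rose by at least 0.14 on the log2 scale. The largest falls were Sox3 (at least 19.4-fold), Porcn (9.83-fold), Kitl (at least 8.78-fold), Nobox, Serpina1b (at least 6.47-fold) and Gdf9. Sox3 and Kitl were above background on 1 of 2 POF arrays. Kitl encodes KIT ligand, a granulosa cell signal to the oocyte; its other probes changed by -0.71 and 1.08, and of those of Serpina1b 1 was at least 3.29-fold lower, below background in POF, and 1 changed by 0.07. Without 1 of the WT or POF arrays the count of genes was 558 (WT replicate 2), 640 (WT replicate 3), 704 (POF replicate 2) or 564 (POF replicate 3).

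The oocyte, general germ cell and meiosis lists fell in POF; the spermatogonia and spermatid lists did not pass. Of 35 measured oocyte genes, 20 were lower, 1 was higher and 14 did not pass; adjusted over the list alone, 27 were lower and 1 was higher. Their median log2 change was -0.91 (adjusted p = 4.18e-14; adjusted p = 0.0542 with an estimated correlation). Beside Gdf9 and Nobox, Zp1 fell 3.71-fold. In the general germ cell list 6 of 12 were lower, and 6 adjusted over the list alone, with a median of -0.67 (adjusted p = 0.000836; adjusted p = 0.288 with an estimated correlation). They included Sohlh2 (-1.62 ± 0.17 SE, n = 2), Sohlh1 (-1.48 ± 0.17) and Kit (-1.23 ± 0.18), of which Kit has a second probe, below background in WT, that rose by at least 0.62. Ddx4, an RNA helicase of germ cells, was 2.59-fold lower (adjusted p = 0.00410). In the meiosis list 7 of 10 genes were lower, and 7 adjusted over the list alone, with a median of -0.94 (adjusted p = 6.79e-05; adjusted p = 0.109 with an estimated correlation). Sycp1 (-1.53), Sycp3 (-1.30) and Stra8 (-1.24) were among them.

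Cell cycle genes were lower in POF at 17 of 28, and 1 was higher; adjusted over the list alone, 21 were lower and 1 was higher. Their median was -0.81 (adjusted p = 5.27e-09; adjusted p = 0.0661 with an estimated correlation). Aurkb, a mitotic kinase, fell by 1.35 and Mcm5, a replication factor, fell by 1.33 on the log2 scale, while Cdca8 rose by 1.19 on its brightest probe and has a second probe at -1.14. Granulosa genes had a median of -0.41, or -0.28 with genes below background at their bound: 4 of 23 were lower and 1 was higher, against 5 and 1 adjusted over the list alone (adjusted p = 0.0237; adjusted p = 0.481 with an estimated correlation). Kitl and the gap junction gene Gja1 (-0.65) were lower, Gpc3 was higher (0.70), and the receptor gene Fshr was at -0.15 (adjusted p = 0.623). The granulosa call ended without WT replicate 3 (adjusted p = 0.0676) or POF replicate 2 (0.0720), with a detection p under 0.01 on all arrays (0.278) and with all 9 columns (0.0512).

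Macrophage genes rose in POF at 13 of 24, and 16 adjusted over the list alone, with a median of 0.84 (adjusted p = 5.89e-12; adjusted p = 0.0542 with an estimated correlation). Gpnmb was 8.84-fold higher, the class II gene H2-Eb1 was 5.42-fold higher, and H2-Aa, below background in WT, was at least 4.85-fold higher. Of the list's genes, 4 are class II genes or their chaperone. Whether H2-Aa follows cell number or genetic background, weighed below, cannot be told apart. Another class II gene outside the list, H2-Ea, chosen after its values were seen, went the other way and was above background on all WT and SSCTR arrays and on neither POF array. Oviduct genes rose at 7 of 14, with a median of 1.17, also with genes below background at their bound (adjusted p = 2.40e-09; adjusted p = 0.0605 with an estimated correlation). Adjusted over the list alone, 11 were higher and 1 was lower. Dynlrb2, a dynein light chain of cilia, was at least 10.1-fold higher. Surface epithelium genes rose at 9 of 16, with a median of 0.76 (adjusted p = 1.25e-08; adjusted p = 0.128 with an estimated correlation), and adjusted over the list alone 13 were higher and 1 was lower. Upk1b was 8.86-fold, Krt7 5.32-fold and Krt19 3.58-fold higher; both keratins belong to simple epithelia. Sertoli cell genes rose at 3 of 12, and 5 adjusted over the list alone, with a median of 0.23, or 0.10 with genes below background at their bound (adjusted p = 0.0379; adjusted p = 0.265 with an estimated correlation). These were Cst9 (at least 2.64-fold), Rhox5 (2.40-fold) and Trf (1.88-fold). The Sertoli call ended without background correction (adjusted p = 0.106), with the authors' values (0.107), an offset of 50 (0.0614) or a detection p under 0.01 on all arrays (0.480), and without WT replicate 2 (0.0639) or POF replicate 3 (0.0683).

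The other lists were not past the threshold in POF against WT, though the respiratory chain and immediate early lists passed it under some alternatives (respiratory chain with an adjusted p of 0.00439 to 0.0414 under 4, immediate early with 0.0143 to 0.0415 under 3). Luteal genes (2 of 15 lower, 5 adjusted over the list alone) had a median of 0.01 but a mean of -0.09, the direction of the test. Cyp11a1, which starts steroid synthesis, was at -0.83 and Scarb1 at -0.64, both past the threshold, with other probes at 0.24 or below for Cyp11a1 and up by at least 0.38 for Scarb1, there above background on 1 of 2 WT arrays; Star was at 0.33 (adjusted p = 0.317). In the theca list 2 of 11 were lower, and 2 adjusted over the list alone: Cyp17a1, the androgen-synthesis enzyme (-0.83), and Hao2 (-0.74). Collagen matrix genes went both ways (3 higher and 2 lower of 23; 4 and 3 adjusted over the list alone), with Col6a2 at 1.26. Spermatogonia genes did too (3 and 4 of 17; 6 and 5 adjusted over the list alone), with Itga6 at 0.99 or more (above background on 1 of 2 WT arrays) and Dnd1 at -1.12. Of 24 interferon genes 2 were higher and 1 was lower, with the same counts adjusted over the list alone; Rsad2 was at 1.24. Of 17 immediate early genes, which also follow tissue handling, 2 were higher, and 2 adjusted over the list alone: Klf6 (0.95) and Fos (0.85).

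Among the remaining lists in POF against WT, endothelial genes were 2 higher and 1 lower of 19 (4 and 1 adjusted over the list alone), with Plvap at 1.34 and Eng at -0.80. Smooth muscle genes were 2 lower of 14 (5 adjusted over the list alone), with Tpm2 at -0.89 and Tagln at -0.84. The second probe of Tpm2, above background on 1 of 2 POF arrays, had a bound of 0. Adipoq (0.87) was the 1 of 12 adipocyte genes to pass, also adjusted over the list alone. The p53 targets Cdkn1a (-0.89) and Ckap2 (-0.88) were the 2 of 19 to pass, also adjusted over the list alone; other probes of Cdkn1a were at 0.17 and 0.89. In the lymphocyte list Cd3g was higher (0.74) and Cd79b lower (-1.51), 1 each of 12, also adjusted over the list alone. Ribosomal protein genes were 2 higher and 2 lower of 47 (2 and 1 adjusted over the list alone), with Rpl29 at 0.95 and Rps6 at -1.73. Of 56 respiratory chain genes Ndufb10 passed (by at least 0.84, above background on 1 of 2 WT arrays; second probe, above background on 1 of 2 POF arrays, at -0.62 or lower) and 0 adjusted over the list alone. Hspb1 (1.30) was the 1 of 10 heat shock genes to pass; adjusted over the list alone, 1 was higher and 1 lower. None of the measured cholesterol synthesis (17), hedgehog (9), erythroid (8) and spermatid (5) genes passed, and 0 adjusted over the list alone in each. Their brightest members Fdps, Ihh, Hbb-bt and Crem were at 0.10, 0.30, 0.09 and 0.43. Other probes were at -0.45 (Fdps), -0.28 (Ihh) and 0.04, -0.20 and 0.73 (Hbb-bt). Those of Crem were at -0.17 or lower, at a bound of 0 and at 0.08.

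**Figure D1:**
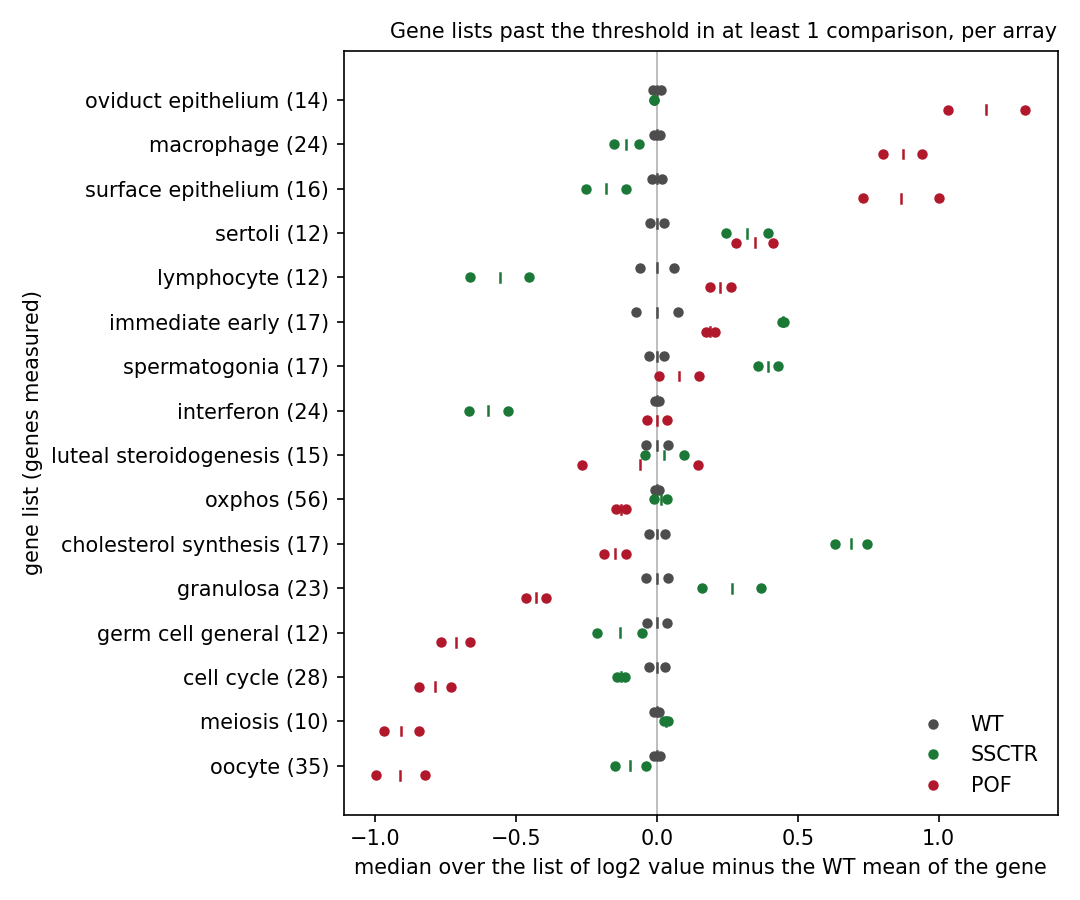
For each list past the threshold in at least 1 comparison, points give 1 array each as the median over the list of log2 value minus the WT mean of the gene, and bars the mean of the 2 arrays of a group; the number of measured genes is in brackets. POF arrays lie at -0.997 and -0.82 for oocyte genes and at 1.31 and 1.03 for oviduct genes, while SSCTR arrays lie at -0.04 and -0.15 and at -0.01 and -0.01.

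The comparison of SSCTR with POF asks how ovaries of transplant recipients differed from the failure model. Oocyte, meiosis, cell cycle and cholesterol synthesis genes were higher in SSCTR, and macrophage, oviduct, surface epithelium and interferon genes were lower. With an estimated correlation only the oocyte and macrophage calls hold (adjusted p = 0.0499 each); the others are lost, with adjusted p = 0.0729 (meiosis), adjusted p = 0.0729 (cell cycle), adjusted p = 0.0688 (cholesterol synthesis), adjusted p = 0.0633 (oviduct), adjusted p = 0.0865 (surface epithelium) and adjusted p = 0.0729 (interferon). Nobox was 5.81-fold higher in SSCTR than in POF (8.10 ± 0.08 against 5.56 ± 0.14, SD, n = 2) and Gdf9 was 2.79-fold higher (8.84 ± 0.07 against 7.35 ± 0.10). Ovgp1 was at least 84.5-fold lower in SSCTR on its brightest probe, with the second, below background in SSCTR, at -0.02 or lower, and Ltf was 67.5-fold lower.

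Past the threshold were 1405 genes, 605 higher and 800 lower in SSCTR, and 690 of them changed at least 2-fold (246 up, 444 down). So did 340 probes without a single symbol. The balance of named genes turned here too with a detection p under 0.01 on all arrays, to 642 higher and 589 lower in SSCTR. The largest rises were Bpifb6 (42.9-fold), Kitl (at least 21.9-fold, above background on 1 of 2 POF arrays; other probes 0.10 and 1.45), Rln1 (relaxin, by at least 3.46 on the log2 scale), Pik3c2g (8.36-fold), H2-Ea (at least 5.96-fold) and Nobox. The largest falls were A2ml1 (at least 78.4-fold), Ovgp1, Ltf, Padi1 (at least 17.3-fold), Mia (19.8-fold) and Wfdc15b (at least 10.3-fold; second probe, below background in SSCTR, at -0.03 or lower). Without 1 array the count was 818 (SSCTR replicate 2), 739 (SSCTR replicate 3), 792 (POF replicate 2) or 678 (POF replicate 3).

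Of the 35 oocyte genes 21 were higher in SSCTR than in POF and 1 was lower, against 27 and 1 adjusted over the list alone, with a median of 0.80 (adjusted p = 8.00e-12; adjusted p = 0.0499 with an estimated correlation). Rfpl4 was 2.71-fold higher and Zp3 1.69-fold higher (adjusted p = 0.0320). Germ cell genes were higher at 6 of 12, and 10 adjusted over the list alone, with a median of 0.86 (adjusted p = 1.16e-05; adjusted p = 0.153 with an estimated correlation). Sohlh2 (1.91 ± 0.17 SE, n = 2), Tex14 (1.70 ± 0.19) and Sohlh1 (1.11 ± 0.17) were among them, and Ddx4 was 1.87-fold higher (adjusted p = 0.0242). Meiosis genes were higher at 6 of 10, and 7 adjusted over the list alone, with a median of 0.72 (adjusted p = 1.16e-05; adjusted p = 0.0729 with an estimated correlation); Sycp1 rose 3.94-fold, Dmc1 2.40-fold and Sycp3 1.75-fold. Spermatogonia genes were 6 higher and 1 lower of 17, with the same counts adjusted over the list alone, and a median of 0.34, or 0.27 with genes at their bound (adjusted p = 0.0164; adjusted p = 0.155 with an estimated correlation). Sall4 (1.03), Dnd1 (0.96) and Taf7l (at least 1.54-fold) were higher; Sall4 is also expressed by oocytes. The spermatogonia call ended without POF replicate 2 (adjusted p = 0.0512) and with a detection p under 0.01 on all arrays (0.0687).

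Cell cycle genes were 16 higher and 2 lower of 28 (18 and 2 adjusted over the list alone), with a median of 0.80 (adjusted p = 2.69e-07; adjusted p = 0.0729 with an estimated correlation); Kif11 was 2.85-fold and Mcm5 2.04-fold higher. Cholesterol synthesis genes were higher at 9 of 17, and 11 adjusted over the list alone, with a median of 0.81 (adjusted p = 3.26e-07; adjusted p = 0.0688 with an estimated correlation). Hsd17b7 rose 3.06-fold, Dhcr7 2.41-fold and Cyp51 2.01-fold. Granulosa genes were higher at 8 of 23 (9 higher and 1 lower adjusted over the list alone), with a median of 0.46 (adjusted p = 0.000973; adjusted p = 0.235 with an estimated correlation). Beside Kitl, the estrogen receptor gene Esr2 rose 2.36-fold, Fst rose 2.31-fold, and Fshr rose 1.55-fold (adjusted p = 0.0385). Luteal genes were higher at 4 of 15, and 6 adjusted over the list alone, with a median of 0.33 (adjusted p = 0.0264; adjusted p = 0.389 with an estimated correlation). Star, which carries cholesterol into mitochondria, and Sfrp4 were both 1.96-fold higher. The luteal call ended without SSCTR replicate 2 (adjusted p = 0.0562) or POF replicate 3 (0.117). Cyp17a1 was at 0.56 (adjusted p = 0.0821).

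Macrophage genes were lower in SSCTR than in POF at 15 of 24, and 18 adjusted over the list alone, with a median of -1.07 (adjusted p = 2.43e-12; adjusted p = 0.0499 with an estimated correlation). Fcer1g was 9.77-fold, Gpnmb 4.85-fold and H2-Eb1 4.75-fold lower. Of the list's genes, 4 are class II genes or their chaperone, and H2-Ea, a class II gene outside the list, was higher. Oviduct genes were lower at 9 of 14, and 10 adjusted over the list alone, with a median of -1.16 (adjusted p = 3.53e-09; adjusted p = 0.0633 with an estimated correlation). Lcn2 was 9.84-fold and the tight junction gene Cldn3 at least 5.14-fold lower. Surface epithelium genes were 11 lower and 1 higher of 16 (14 and 1 adjusted over the list alone), with a median of -0.99 (adjusted p = 3.53e-09; adjusted p = 0.0865 with an estimated correlation); Krt18, Krt7 and Krt19 were 6.50-fold, 6.43-fold and 6.06-fold lower. Interferon genes were 11 lower and 1 higher of 24 (12 and 1 adjusted over the list alone), with a median of -0.67 (adjusted p = 8.70e-05; adjusted p = 0.0729 with an estimated correlation); Rsad2 and Cxcl9 were 4.27-fold and 2.04-fold lower, and Cxcl10, above background on 1 of 2 SSCTR arrays, at least 2.39-fold lower. Lymphocyte genes were lower at 4 of 12, and 5 adjusted over the list alone, with a median of -0.50 (adjusted p = 0.00771; adjusted p = 0.235 with an estimated correlation); Cd3g fell 2.82-fold and Coro1a 2.15-fold.

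Respiratory chain genes had a median of 0.15 (adjusted p = 0.0191; adjusted p = 0.144 with an estimated correlation), with Sdhc the 1 of 56 to pass (0.71) and 0 adjusted over the list alone; the call ended with a detection p under 0.01 on all arrays (adjusted p = 0.130). Immediate early genes, which follow tissue handling, were 5 higher and 1 lower of 17 (7 and 1 adjusted over the list alone), with a median of 0.37 (adjusted p = 0.0264; adjusted p = 0.297 with an estimated correlation). Egr3 rose 4.16-fold, Fos 2.08-fold and Jun 1.92-fold. This call ended without SSCTR replicate 3 (adjusted p = 0.0929) or POF replicate 2 (0.0832), with a detection p under 0.01 on all arrays (0.0504) and with all 9 columns (0.0656).

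Of the lists not past the threshold in SSCTR against POF, Sertoli genes were 4 higher and 2 lower of 12 (5 and 2 adjusted over the list alone), with Defb36 at 1.28 (other probe, above background on 1 of 2 SSCTR arrays, at -0.08 or lower), Aard at 1.18 and Trf at -2.17. Collagen matrix genes were 5 higher and 3 lower of 23 (5 and 9 adjusted over the list alone), with Tnc at 1.39 and Col6a2 at -1.41. Endothelial genes were 3 higher and 2 lower of 19, with the same counts adjusted over the list alone; Plvap was at -1.49 and Kdr at 0.69. Smooth muscle genes were 3 higher of 14 (4 adjusted over the list alone), with Rgs5 at 1.35. Of 19 p53 targets 2 were lower (1 higher and 3 lower adjusted over the list alone), with Ddit4 at -0.82. Heat shock genes were 1 higher and 1 lower of 10, also adjusted over the list alone: Hspe1 (0.99) and Hspb1 (-1.09). Adipoq (-0.96) and the hedgehog gene Cdon (-0.72) were the only members of their lists to pass, also adjusted over the list alone, while Rpl29 (-0.76), the 1 ribosomal protein gene to pass, left 0 adjusted over the list alone. Theca, erythroid and spermatid lists had no gene past the threshold and 0 adjusted over the list alone. Acta2, Hbb-bt and Crem, their brightest members, were at -0.10, 0.18 and 0.23. Other probes of Hbb-bt were at 0.38, at -1.39 and, below background in SSCTR, at -0.06 or lower. The median, mean and direction of the test differed in sign for 3 lists, none of them past the threshold.

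The comparison of SSCTR with WT asks what set recipient ovaries apart from wild type. Cholesterol synthesis, Sertoli, spermatogonia and immediate early lists were higher in SSCTR, and interferon and lymphocyte lists were lower. None of these calls holds with an estimated correlation: adjusted p = 0.122 for the cholesterol synthesis and interferon lists, adjusted p = 0.236 for the Sertoli, spermatogonia and immediate early lists, and adjusted p = 0.316 for the lymphocyte list. Cyp51, a sterol demethylase, was 2.36-fold higher (10.74 ± 0.05 against 9.50 ± 0.15, SD, n = 2), and Star was 2.48-fold higher (9.41 ± 0.15 against 8.10 ± 0.24). Gdf9 was 2.44-fold lower (adjusted p = 0.00533), while Zp3, Ddx4, Fshr and Cyp17a1 were at -0.59, -0.47, 0.48 and -0.26 with adjusted p = 0.144, 0.287, 0.168 and 0.512.

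In SSCTR against WT 347 genes passed, 196 higher and 151 lower, of which 230 changed at least 2-fold (130 up, 100 down); 112 probes without a single symbol passed too. The largest rises were 2810025M15Rik (12.3-fold), Bpifb6 (11.5-fold), Megf10 (at least 7.44-fold), Rln1 (3.33 on the log2 scale), Nat8 (at least 7.95-fold) and Olfml2b (at least 6.57-fold). The largest falls were Sox3 (10.5-fold), Serpina3n (5.09-fold), Fbxo2 (at least 4.72-fold, above background on 1 of 2 SSCTR arrays), Xpnpep2 (4.59-fold), Acvr2a (an activin receptor, 4.03-fold) and Adh7 (at least 3.01-fold). The count was 710 without background correction, 709 with the authors' normalized values, 627 with an offset of 50 and 676 with an intensity trend. Without 1 array it was 96 (WT replicate 2), 104 (WT replicate 3), 106 (SSCTR replicate 2) or 101 (SSCTR replicate 3).

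Cholesterol synthesis genes were higher in SSCTR than in WT at 3 of 17, and 9 adjusted over the list alone, with a median of 0.58 (adjusted p = 2.50e-07; adjusted p = 0.122 with an estimated correlation). These were Cyp51, Hsd17b7 (2.30-fold) and Fdps (1.97-fold). Sertoli genes were 4 higher and 1 lower of 12 (5 and 1 adjusted over the list alone), with a median of 0.40, or 0.20 with genes at their bound (adjusted p = 0.00262; adjusted p = 0.236 with an estimated correlation). Of these 12 genes, 8 were above background on both WT arrays. The list's median lay above WT without a transplant as well: it was 0.39 and 0.25 on the SSCTR arrays and 0.41 and 0.28 on the POF arrays. The members differed between these groups, however. In SSCTR against POF 4 were higher and 2 lower, with a median change of 0.40 (camera adjusted p = 0.140, not past the threshold). Against WT, Cst9 was at least 6.09-fold, Defb36 3.64-fold and Aard 2.36-fold higher in SSCTR. The call ended with a detection p under 0.01 on all arrays (adjusted p = 0.159). Spermatogonia genes were 2 higher and 1 lower of 17 (8 and 2 adjusted over the list alone), with a median of 0.40 (adjusted p = 0.00819; adjusted p = 0.236 with an estimated correlation). Those that passed were Itga6, an integrin of many epithelia (at least 3.41-fold higher, above background on 1 of 2 WT arrays), Taf7l (at least 1.54-fold higher) and Thy1, which lymphocytes also carry (2.35-fold lower). The spermatogonia call ended with the mean over a gene's probes (adjusted p = 0.0839).

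Immediate early genes were higher at 5 of 17, and 7 adjusted over the list alone, with a median of 0.47 (adjusted p = 1.72e-05; adjusted p = 0.236 with an estimated correlation). Egr3, above background on 1 of 2 WT arrays, rose at least 5.24-fold, Fos 3.74-fold and Jun 2.27-fold. Interferon genes were lower at 5 of 24 (1 higher and 15 lower adjusted over the list alone), with a median of -0.60, or -0.54 with genes below background at their bound (adjusted p = 2.48e-07; adjusted p = 0.122 with an estimated correlation); Psmb8, Ifit3 and Gbp2 fell 1.87-fold, 1.84-fold and 1.76-fold. The other probe of Psmb8 was at 0.01. Lymphocyte genes were lower at 2 of 12, and 5 adjusted over the list alone, with a median of -0.57, or -0.45 with genes below background at their bound (adjusted p = 0.00393; adjusted p = 0.316 with an estimated correlation). They were Cd79b (at least 2.72-fold, above background on 1 of 2 SSCTR arrays) and Coro1a (1.89-fold), and the call ended with a detection p under 0.01 on all arrays (adjusted p = 0.0660).

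Oocyte genes had a median of -0.03 in SSCTR against WT, with 2 of 35 lower, and 2 adjusted over the list alone: Gdf9 and Oas1d (-1.07). That list was not past the threshold (adjusted p = 0.0699). It passed, lower in SSCTR, under 6 alternatives: without background correction (0.0248), with the authors' values (0.0249), an offset of 50 (0.0443), no detection filter (0.00498) or the mean over a gene's probes (0.0279), and without SSCTR replicate 2 (0.0394). In the general germ cell list Tex14, a protein of germ cell bridges, was 3.97-fold higher, the 1 of 12 to pass, also adjusted over the list alone. Meiosis genes had 0 of 10 past the threshold and 0 adjusted over the list alone, with Msh4 at 0.33. Granulosa genes had 2 higher of 23 (4 higher and 1 lower adjusted over the list alone), Kitl (1.32, other probes -0.61 and 2.53) and Fst (0.80); that list was not past the threshold, but passed under 5 alternatives (adjusted p of 0.00853 to 0.0458). Luteal genes had 4 higher of 15 (4 higher and 1 lower adjusted over the list alone), among them Star, Ptgfr (1.22) and Hsd17b7; the list passed with the mean over a gene's probes (adjusted p = 0.0392). Collagen matrix genes had 3 higher of 23 (4 higher and 1 lower adjusted over the list alone), with Tnc at 2.26 and Ccn2 at 1.44. Macrophage genes had 1 higher and 1 lower of 24 (2 and 1 adjusted over the list alone), Gpnmb (0.87) and Fcer1g (-1.29).

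In the remaining lists of SSCTR against WT, 1 or 2 genes passed or none did. Bub1b (0.83, other probe at -0.10) was the 1 of 28 cell cycle genes, also adjusted over the list alone, and Cdkn1a (-0.83, other probes at 0.57 and above) and Ddit4 (-0.80) were the 2 of 19 p53 targets (2 higher and 4 lower adjusted over the list alone). Tek (0.95) was the 1 of 19 endothelial genes and Rgs5 (1.49) the 1 of 14 smooth muscle genes, with 1 higher and 1 lower adjusted over the list alone in each. Rps6 (-1.18) was the 1 of 47 ribosomal protein genes, also adjusted over the list alone, and Ndufb10 (at least 1.01, above background on 1 of 2 WT arrays, other probe at -0.20) the 1 of 56 respiratory chain genes, with 0 adjusted over the list alone. Oviduct (14), surface epithelium (16), theca (11), hedgehog (9), heat shock (10), adipocyte (12), erythroid (8) and spermatid (5) lists had 0 past the threshold. Adjusted over the list alone, 2 oviduct, 2 surface epithelium and 1 hedgehog genes were lower and 1 spermatid gene was higher, and 0 in the others. Lcn2, Igfbp5, Acta2, Ihh, Hspa8, Lpl, Hbb-bt and Crem, named for these lists, were at 0.06, -0.04, 0.13, 0.20, -0.26, 0.55, 0.26 and 0.67. Other probes of Hbb-bt were at 0.42, at -0.67 and, below background in SSCTR, at -0.26 or lower. That of Ihh was at 0.90, those of Igfbp5 at -0.17 and 0.14, and those of Crem at -0.23 or lower, 0.06 or more and 0.35. The median, mean and direction of the test differed in sign for 9 lists, none of them past the threshold.

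The last comparison asks how genes changed in POF stood in SSCTR. Of the 1312 genes, 780 (59.5%) also passed the threshold in SSCTR against POF in the opposite direction, among them Gdf9, Nobox, Ovgp1 and Gpnmb. They made up 515 of the 745 genes higher in POF and 265 of the 567 lower ones. The same direction was found for 13 genes. The SSCTR mean lay nearer the WT than the POF mean for 973 of the 1312 (74.2%). Lists drawn independently would share 85.0 genes, but the comparisons share the POF arrays, which alone tends to give opposite changes. Over all genes the log2 changes had a covariance of -0.222 and a correlation of -0.742, against -0.0223 and -0.500 in 100 simulations of unchanged groups; how many of the 780 the sharing contributes was not measured. Without 1 array the count of 780 was 424 (WT replicate 2), 445 (WT replicate 3), 516 (SSCTR replicate 2), 499 (SSCTR replicate 3), 448 (POF replicate 2) or 371 (POF replicate 3).

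Changed the same way in POF and SSCTR against WT were 127 genes, where independent lists would share 20.96; these comparisons share the WT arrays. Without 1 array the count of 127 was 34 to 75, and it was 302 without background correction, 301 with the authors' values, 258 with an offset of 50 and 266 with an intensity trend. Sox3, 2810025M15Rik and Cst9 were among them. Over all genes the covariance of these changes was 0.0685, above the 0.0223 in the simulations, while their correlation was 0.322, below the 0.499 that sharing gives unchanged groups. Of the 347 genes changed in SSCTR against WT, 202 did not pass in POF against WT, and 149 of these passed in the same direction against POF as well, Star and Egr3 among them. These counts were 360 and 235 without background correction and with the authors' values alike, and 363 and 219 with an intensity trend. Without 1 array these counts fell to between 43 and 183, and between 36 and 89. The difference between the lists of genes was not tested.

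**Figure D2:**
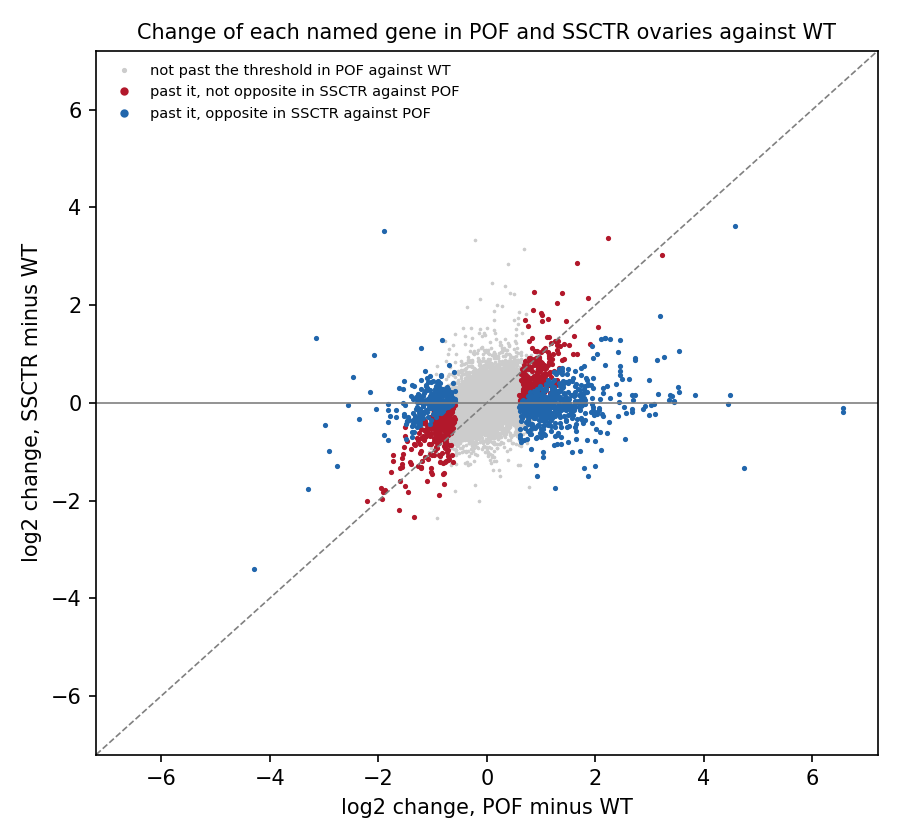
Each point is 1 of the 11053 named genes, with its log2 change in POF against WT on the horizontal and in SSCTR against WT on the vertical axis. Genes in blue are the 780 that changed in the opposite direction in SSCTR against POF; a gene on the diagonal changed by the same amount in both groups, and 1 on the horizontal line did not differ between SSCTR and WT.

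Because the transplanted cells come from the testis, genes of the Y chromosome were measured as a sign of male cells. The array holds 17 probes of 10 such genes, and none passed the detection filter. Of 102 values on the 6 arrays 2 were above background, 1 in WT and 1 in POF, and 0 of 34 in SSCTR, where chance gives 5.1 in all. The mean of the probes in SSCTR exceeded that in the other groups by 0.02 on the log2 scale (4.42 ± 0.01 with n = 2 against 4.40 ± 0.02 with n = 4, SD), with a two-sided exact permutation p = 0.333; the smallest that the 15 splits allow is 0.0667. Y-linked RNA was thus not detectable above background on these arrays. No male sample was measured, so how much Y-linked RNA these probes would show is not known, and male cells are not excluded. Eif2s3y, with 2 probes, and Amh, the anti-Mullerian hormone of granulosa cells, with 1, were not above background on enough arrays to be tested.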

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

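Both tests in this part were chosen after the values were seen. The columns of replicate 1 are not used by the comparisons. For 100% of probes with a detection p above 0 in WT, 100% in SSCTR and 100% in POF, the ratio of replicate 1 to the mean of replicates 2 and 3 was the same in signal and in detection p, within a tolerance of 1e-04 of the ratio. In the columns of replicates 2 and 3, set against the other columns in the same way, at most 0.0234% of probes did so. The detection p-values of replicate 1 lie above 1 for 526 probes in WT, 374 in SSCTR and 153 in POF, and reach 1.13, 1.11 and 1.08.

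As to where these columns come from, the ratio takes 6 values in WT, 17 in SSCTR and 9 in POF, from 0.908 to 1.13, and is constant over runs of consecutive probes of the table (223, 280 and 227 runs). A separately measured array would hold no detection p above 1, as none of the other columns does, and the 1053 such values argue against it. That the columns were computed from replicates 2 and 3 fits the 100% of probes that share the factor. The design gives no biological explanation to test, and why the columns were made is not given in the sources used here. The groups were therefore compared with 2 arrays each.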

How the results depend on the processing

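The fit of all 9 columns, and the Y-linked value under normalizations other than the authors' and the raw intensities, were added after the data were seen. Of 187 calls of named genes, 184 kept their direction under every alternative in which the gene was tested, and 100 also kept the threshold. Of 30 list calls, 30 and 2 did. A gene with no probe at a detection p under 0.01 on all arrays was not tested under that alternative. Its call counts as kept there, which holds for genes seen in 1 group only. Of the genes past the threshold, this alternative tested 917 in POF against WT, 952 in SSCTR against POF and 248 in SSCTR against WT. Calls of named genes ended or turned for 80 with 1 array left out, where the lone array of a group is assumed to vary like the others, for 58 with a 2-fold minimum, 23 without the detection filter, 21 with the mean over a gene's probes, 21 with replicate number as a block and 19 with the arrays of the groups compared alone. Kitl turned to 1.08 in POF against WT with a detection p under 0.01 on all arrays, since another of its probes then stood for it. Cdkn1a turned to 0.056 in POF against WT and to 0.42 in SSCTR against WT with the mean over its probes, which differ in sign. Of the list calls, 28 ended with an estimated correlation, which left 0 lists in POF against WT, 2 in SSCTR against POF and 0 in SSCTR against WT; 7 ended with a detection p under 0.01 on all arrays and 5 with 1 array left out.

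Counts are given in the order POF against WT, SSCTR against POF, SSCTR against WT, opposite in SSCTR against POF, and the same way in both against WT (1312, 1405, 347, 780 and 127). With a 2-fold minimum they were 627, 690, 230, 396 and 69, fewer by construction. With all 9 columns they were 4011, 4028, 2526, 2320 and 1050, where computed columns count as arrays and narrow the spread. With replicate number as a replicate block the first 3 were 1128, 1226 and 262. With 1 array left out they ranged from 558 to 1214, 678 to 1240, 96 to 264, 371 to 516 and 34 to 75. Named by array left out, the count in POF against WT was 558 (WT 2), 640 (WT 3), 704 (POF 2) and 564 (POF 3). That in SSCTR against POF was 818 (SSCTR 2), 739 (SSCTR 3), 792 (POF 2) and 678 (POF 3), and that in SSCTR against WT 96 (WT 2), 104 (WT 3), 106 (SSCTR 2) and 101 (SSCTR 3). SSCTR against WT rose to 710 without background correction, 709 with the authors' values, 627 with an offset of 50 and 676 with an intensity trend, and the count changed the same way in both to 302, 301, 258 and 266; the cause was not tested.

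The mean correlation of SSCTR with WT exceeded that with POF by 0.0180. It exceeded it by 0.0146 without background correction and with the authors' values alike, by 0.0156 with an offset of 50, by 0.0101 without the filter, by 0.0196 with 9 columns, and by 0.0163 to 0.0196 with 1 array left out. The Y-linked difference of 0.0156 was 0.0329 with 9 columns, where the exact permutation p of 0.0476 counts computed columns as arrays. It was 0.00212 with the authors' values, 0.00237 without background correction, 0.00672 with an offset of 50, 0.0250 with median scaling and 0.00898 to 0.0222 with 1 array left out. As raw intensity minus the array median, on another scale, it was 0.223. The exact permutation p was 0.2 or more in each of these. Signal over background limits the dim genes: no probe of the 10 Y-linked genes or of Amh passed the detection filter, and genes below background on an array of the dimmer group are given as bounds.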

Other observations

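The tests on silent genes not looked at before, on probes that follow their gene, on neighbouring genes, on added ciliated cell genes and on added mast cell genes were written before their results were seen; the other tests here were chosen afterwards, as were the genes named here. Genes of the kallikrein 1 family, secreted proteases, were higher in POF than in WT at 5 of the 6 members that passed the detection filter, and lower in SSCTR than in POF at the same number; the array holds 12, and the filter favours members high in POF, since only 1 of the 6 is above background in WT. With the other 5 at their bound the median log2 change in POF against WT was 2.22. Klk1b27, the member above background, was at 3.54 ± 0.27 (SE, n = 2), and its other probe, below background in WT, at 1.63 or more; Klk1b21 was at least 6.85-fold higher (other probes, also below background in WT, up by at least 0.35 and 0) and Klk1 at least 4.18-fold, while the other probes of Klk1b5 and Klk1b26 were below background in all groups, so that their change was not measured. Their sequences are close, and probes of the family can share signal.

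The mast cell protease genes Cpa3, Cma1, Cma2, Mcpt4 and Tpsb2, picked after their values were seen, were lower than in WT in both other groups. Cpa3 was at -1.60 ± 0.22 (SE) in POF and -1.34 in SSCTR against WT. Cma1 was at least 3.54-fold lower in POF and 3.42-fold lower in SSCTR, Mcpt4 at least 2.75-fold and 2.51-fold, and Tpsb2 at least 2.13-fold and 2.08-fold, all past the threshold; each of these 3 is below background on 1 or both arrays of POF and SSCTR. A lower number of mast cells in both groups may account for this. Of the added mast cell genes, 10 were measured, of which WT expresses 8 and other lists hold 2. Their median was -0.39 in POF and -0.24 in SSCTR against WT, or -0.27 and -0.09 with genes at their bound (camera of limma, adjusted p = 0.215 and adjusted p = 0.14 over the 3 list tests written before), with Mrgprb2 at least 1.82-fold and 1.67-fold lower but Hdc at 1.03 in POF, so the question stays open. Of the proteases among them, Tpsab1 was lower past the threshold in POF but not in SSCTR against WT (adjusted p = 0.00741 and 0.0856). Mcpt8 passed in neither (adjusted p = 0.0590 and 0.905).

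Oviduct genes in POF, of which 9 of 14 are above background in WT and 1 stands in another list, were weighed against tissue and processing. The background correction or normalization run here is argued against as the cause, since the list stayed past the threshold under 4 other normalizations. Medians were 0.49 to 1.17, with a camera adjusted p of at most 2.16e-09 with the preset correlation. With an estimated correlation the call is lost (adjusted p = 0.0605). All 4 start from deposited values already brought to 1 distribution, so the submitters' own normalization was not tested as a cause. A lower share of the main cell types would raise endothelial, smooth muscle and adipocyte genes as well, but the highest of their medians was 0.19, below the lower quartile of the oviduct list (0.46). Oviduct tissue in the POF samples may be a source: 17 added ciliated cell genes, 11 of them above background in WT, had a median of 0.38 in POF against WT (quartiles 0.12 and 0.69; 0.36, with quartiles 0.06 and 0.49, with genes at their bound; camera of limma, adjusted p = 0.00247, and adjusted p = 0.11 with an estimated correlation), with 4 higher and 1 lower. The array holds 33 of these genes, and the detection filter favours members high in POF. Rsph4a, 1 of the 4 higher, was below background on all WT and SSCTR arrays. Ovgp1 stood at 11.25 in POF on its brightest probe, while its second rose by at least 0.14, and Lcn2 at 10.52; whether the ovary of this model itself expresses them was not tested and stays open.

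H2-Ea and Ifi202b, which mice of strain C57BL/6 are known not to express, were above background on their brightest probes on the WT and SSCTR arrays (8 of 8 values) and on neither POF array (0 of 4; of the other 2 probes of Ifi202b, 1 followed and 1 was above background on 0 arrays), although all samples are labelled with that strain; H2-Ea was at 6.77 ± 1.18 in WT, 7.30 ± 0.05 in SSCTR and 4.31 ± 0.03 in POF (log2, SD, n = 2). Fewer antigen-presenting cells in POF are argued against by the other class II genes and chaperones (median 1.31 higher in POF). That median includes H2-Aa, which is counted below as going with another background. Apart from it, Cd74, H2-DMa and H2-DMb1 were also higher in POF (0.76, 0.81 and 0.76). The normalization run here is argued against by 4 others, under which H2-Ea stayed lower in POF with an adjusted p of at most 0.00714. Its change was -1.10, -1.11, -1.46 and -2.48 under these, against -2.47. These 4 also start from the deposited values, so the submitters' own normalization was not tested here either. A genetic background of the POF mice other than that of the WT and SSCTR mice may explain the pattern. By the test written before, the added gene Gbp2b went against it (4 of 4 WT and SSCTR values and both POF values above background, while Mx1 had none). But 1 gene expressed in all groups cannot tell whether their backgrounds differ, so no conclusion on that is drawn from it. Gbp2b was added as a gene silent in C57BL/6, so its signal is at odds with the strain label in all groups, POF included. The share of probes that did not follow their gene leaves the explanation open (39.3% in POF and 43.2% in SSCTR against WT, Fisher's exact p = 0.496). The share of genes changed in POF against WT that lie next to a changed gene, 26.7%, was within 1000 shuffles (mean 22.3%, highest 27.3%). Its excess over their mean was no larger than in SSCTR against WT (4.41 against 4.56 points, with 10.7% against 6.10% in SSCTR). Going with another background of the POF mice, H2-Aa and 1 of 2 Serpina1e probes, genes picked after their values were seen, were above background on both POF arrays and on 0 of 4 others. The other way round, 2 of 3 Serpina1b probes were so. In SSCTR against POF, not named in the test of neighbours, 32.5% lay next to a changed gene, above all shuffles (mean 23.8%, highest 28.4%). The failure model cannot account for H2-Ea and Ifi202b in WT, which is at odds with the strain label, but why POF lacks them stays open: background and model follow the same groups and cannot be told apart for these genes, which bears on every comparison with POF, the 780 genes opposite in SSCTR included.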
